A study of Homo sapiens with 2 samples.

How the data were processed

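RNA from T24/R cells treated for 6 h with DMSO or with 1600 nM THZ1 was extracted with TRIzol and made into libraries with the KAPA mRNA HyperPrep kit, per the labels' protocols. The kit captures polyadenylated RNA. Each group had 1 library. The deposited values are raw read counts per gene, whole numbers that the authors had not normalized, as the values themselves show. The submitters' processing notes name Trimmomatic 0.38, HISAT2 2.1.0 and featureCounts 1.6.0 and the genome build GRCh38. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without a stated strand setting, counts of antisense and overlapping genes cannot be told apart from those of their partners, and genes with near-identical copies can lose or share reads.

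Each library listed the same 58884 Ensembl gene IDs, of which 58611 were found in GENCODE 29 (GRCh38) and 58472 had a symbol in the symbol table, while 8 were in neither. Coordinates, gene types, spans, transcript lengths and GC content come from GENCODE 29. No value was left out for naming no gene. The libraries were grouped by their treatment label.

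Scaling used TMM factors from edgeR 4.0.16 (R 4.3.3), which gave effective library sizes of 22049153 for DMSO and 15320940 for THZ1. Genes with 30 or more counts in at least 1 library were tested, 12457 in all. The log2 ratio of the THZ1 over the DMSO library was computed from normalized counts with 0.5 added to each count. Its 95% interval is the exact Clopper-Pearson interval of the THZ1 share of both counts, turned into a ratio with the effective library sizes. A gene was called lower or higher when its ratio was at least 2-fold and the interval excluded 1, and neither otherwise. Sequencing reads without molecular identifiers are not independent molecules, so the intervals and floors cover counting error only, and biological variation between cultures is not measured. A floor of 3 counts stands for genes with 0 counts, and no fold is given where both libraries are at or under it.

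The 34 gene lists, the calling rule and the naming rule were fixed before the data were examined, whereas the tests of explanations were set up after the patterns were seen. The rule names the 12 protein-coding genes with the lowest and the 12 with the highest ratio among nuclear genes with 200 or more counts in the library where they are higher, leaving out clone names. It also names up to 3 members of each list with the ratios furthest from 0 among members with 100 or more counts in at least 1 library, and a fixed set of genes around CDK7, Hedgehog signalling and stemness together with ACTB and GAPDH. Members outside the rule (DISP1, ID1, ID2, ID3, FOSB, NR4A1, KLF2, H4C3 and LUM) are named after their values were seen, to complete a small group. Some genes that the rule would name are not reported here. List medians are set against 10000 random lists of the same size drawn from 20 bins of mean expression, and the percentile describes these libraries and is not a test across replicates. An alternative adds 5 bins of gene span to the matching. Lists with fewer than 3 tested members get no percentile.

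The calls were tested on simulated data for DMSO against THZ1, with counts drawn at the real means and library sizes and 200 genes changed. Equal numbers of these were raised and lowered. The effective library sizes were given and not estimated again, so the simulation does not measure errors that come from the scaling. With counting noise alone, over 12267 genes, all genes changed by 1.5 or 3 on the log2 scale were called, 16 of 12067 unchanged genes (0.133%) were called, and the interval covered the true ratio for 95.5% of genes. With an added spread between libraries of 0.2 as a coefficient of variation, 90% of genes changed by −1.5, 80% of those changed by 1.5 and 100% of those changed by −3 or 3 were called. In that setting 357 of 12088 unchanged genes (2.95%) were called and coverage fell to 41.2%, so the intervals are too narrow wherever cultures vary. Of the unchanged simulated lists, 6% fell outside the middle 95% of the random lists, and a list shifted by 1 stood at percentile 100.

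Alternatives were total counts, DESeq2 1.42.0 size factors, the upper quartile and the mitochondrially encoded mRNAs as scaling; count minimums of 1 and 100; protein-coding genes only; an interval bound of at least 2-fold; thinning to equal totals; 5 counts added in place of 0.5; exonic length in place of gene span; and a correction for transcript length and GC content, which was added after the trends were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.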

Results

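RNA was sequenced from T24/R cells, an adherent human bladder line related by name to the urothelial carcinoma line T24, after 6 h with 1600 nM THZ1 or with the solvent DMSO. THZ1 binds covalently to CDK7, the kinase of the general transcription factor TFIIH, and also acts on CDK12 and CDK13. The comparison asks how RNA levels differ after 6 h of THZ1, with stemness genes and the Hedgehog pathway as the focus that the series names. There was 1 library per group and there were no replicates, so the difference has no replicate check and no p-value is given. The DMSO library held 18445831 counts over 23986 genes and the THZ1 library 18313827 counts over 23528 genes. All intervals are 95% intervals. Those of single genes and of shares of counts cover counting error only, and those of medians are order-statistic intervals over genes.

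After 6 h of THZ1, far more genes were lower than higher relative to the bulk of the transcriptome. EFNB2, which encodes the Eph receptor ligand ephrin-B2, was 30.6-fold lower, with a log2 ratio of −4.93 (−5.76 to −4.29; 769 counts in DMSO and 17 in THZ1). The histone H3 lysine methyltransferase gene SUV39H1 was 24.6-fold lower (265 and 7 counts), CDC25A, the phosphatase that activates cyclin-dependent kinases at the start of S phase, was 24.3-fold lower (1312 and 37 counts), and HMOX1, which encodes the haem-degrading enzyme heme oxygenase, was 22.8-fold lower (6675 and 203 counts). The gene with the highest ratio under the naming rule was FOS, a subunit of the AP-1 transcription factor, which was 16.6-fold higher (log2 ratio 4.05, 3.58 to 4.61; 36 and 421 counts). CDK7 itself was 2.60-fold lower. Of 16 tested Hedgehog genes, 4 were lower (PTCH1, SUFU, GLI3 and DISP1), beside 21.3% of all tested genes, while the target gene GLI1 had only 13 and 10 counts.

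The other genes among the 12 with the lowest ratios were TFAP2C (−4.48), CDC42EP4 (−4.37), MAP3K14 (−4.32), ZNF627 (−4.25), DCLRE1B (−4.11), TNFRSF1A (−4.06), FAM83G (−3.93) and PIK3R1 (−3.91). MAP3K14 encodes the kinase NIK of the noncanonical NF-kappaB pathway, TNFRSF1A a receptor for tumour necrosis factor, and PIK3R1 a regulatory subunit of phosphoinositide 3-kinase. On the other side stood FOS, TLCD2 (3.18, 2.86 to 3.54), COX6A1 (2.86, 2.74 to 2.98), the histone gene H2AC8 (2.51), the early response genes JUNB (2.49), EGR1 (2.44) and NR4A2 (2.17), RPS29 (2.15), HLA-B (2.15), COMMD6 (2.14), MICOS10 (2.04) and SEC61G (2.00). These 12 stayed above 0 under each scaling tried. COX6A1, RPS29, H2AC8 and HLA-B have near-identical copies elsewhere in the genome, and MICOS10 overlaps another coding gene, so reads of these genes can be split or shared and their values are uncertain. On GRCh38, EFNB2 (ENSG00000125266) lies on chromosome 13 from 106489731 to 106535662, CDC25A (ENSG00000164045) on chromosome 3 from 48157146 to 48188402, HMOX1 (ENSG00000100292) on chromosome 22 from 35380361 to 35394214 and FOS (ENSG00000170345) on chromosome 14 from 75278774 to 75282230.

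Among 12457 genes with enough counts, 2657 (21.3%) were at least 2-fold lower in THZ1, 1208 (9.70%) were at least 2-fold higher and 8592 were neither. Of the 10881 tested protein-coding genes, 2390 were lower and 828 higher. At 4-fold, 955 genes were lower and 179 higher, and at 8-fold 237 and 67. The median log2 ratio was −0.03 with quartiles at −0.83 and 0.55. These numbers depend on what the libraries are scaled to. All log2 ratios shift by −0.51 when scaled to total counts and by −1.69 when scaled to the mitochondrially encoded mRNAs, which moves the median of all genes to −0.54 and −1.72. Of the genes past the rule, 31.3% were higher and 68.7% lower, against 7.95% and 92.0% with total counts and 0.87% and 99.1% with the mitochondrial reference. A gene higher by less than 1.69 therefore lies below 0 on the mitochondrial reference, and the counts carry no information on the absolute amount of RNA per cell. With total counts the number of lower members was 16 for the transcriptional kinase list, 14 for Wnt components, 12 for p53 targets, 10 for splicing factors, 9 for pro-apoptotic genes, 5 each for anti-apoptotic, nucleotide excision repair and interferon-stimulated genes and 2 each for TFIIH, hypoxia, urothelial and replication-independent histone genes, each over 1.5 times the number given below. The number of higher members was then 10 for ribosomal proteins, 6 for the respiratory chain, 8 for replication-dependent histones, 1 each for chaperones and small nucleolar RNA host genes, and 0 for hypoxia and glycolysis genes, interferon-stimulated genes and 8 of the 10 lists with 1 higher member on the main scaling (Notch, TFIIH, transcriptional kinases, RNA polymerase II, unfolded protein response, nucleotide excision repair, epithelial-mesenchymal transition and replication-independent histones).

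**Figure D1:**
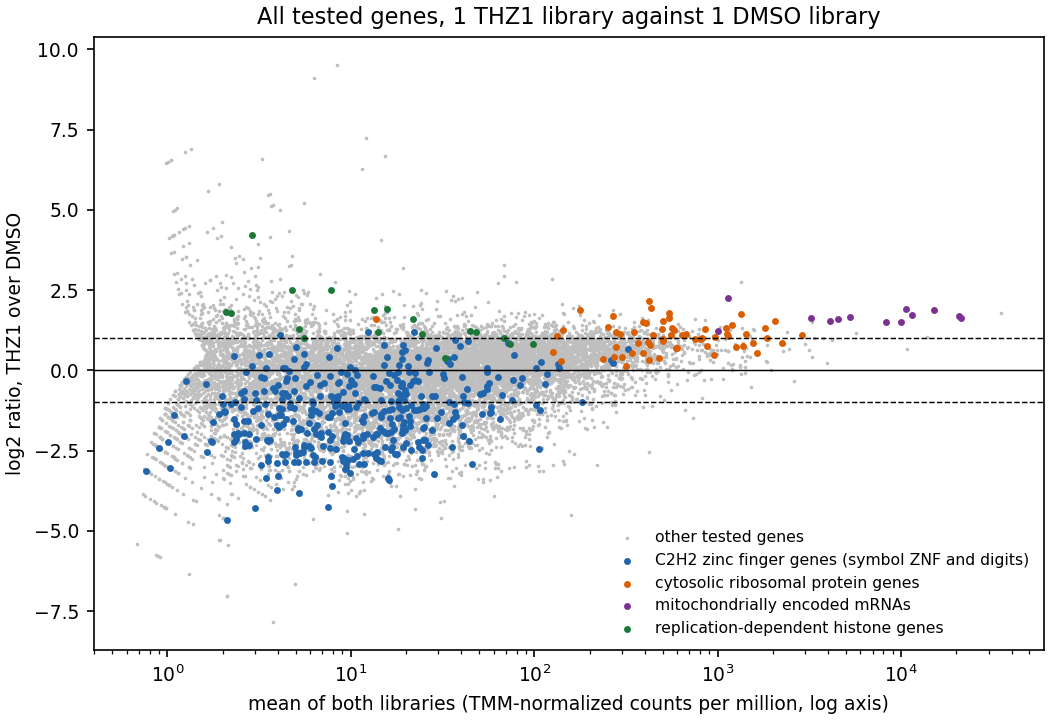
Each point is 1 of the 12457 tested genes: the horizontal axis is the mean level of both libraries in TMM-normalized CPM on a log axis, the vertical axis the log2 ratio of the THZ1 over the DMSO library, and dashed lines mark 2-fold. The zinc finger genes with a symbol of ZNF and digits (blue) lie mostly below 0 with a median of −1.28. Ribosomal protein genes (orange, median 1.06), replication-dependent histone genes (green, 1.26) and mitochondrially encoded mRNAs (purple, 1.64) lie above 0, medians that become −0.63, −0.43 and −0.05 on the mitochondrial reference.

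Hedgehog signalling runs from the receptor PTCH1 through SMO and the inhibitor SUFU to the GLI transcription factors. Of 16 tested Hedgehog components, 4 were lower, 0 were higher and 12 were neither, beside 21.3% lower among all tested genes. With total counts 10 of them were lower and with the mitochondrial reference 15, and 0 were higher with either. On the main scaling the lower genes were DISP1 (−2.66, −3.83 to −1.78), PTCH1 (−2.20, −2.72 to −1.73; 273 and 41 counts), SUFU (−2.15, −2.81 to −1.58; 175 and 27 counts) and GLI3 (−1.41, −1.75 to −1.08; 364 and 95 counts). PTCH1 (ENSG00000185920) spans chromosome 9 from 95442980 to 95517057, SUFU (ENSG00000107882) chromosome 10 from 102503987 to 102633535 and GLI3 (ENSG00000106571) chromosome 7 from 41960950 to 42237870. The signal transducer SMO had a ratio of −0.67 (−1.31 to −0.07; 76 and 33 counts). GLI1, the transcriptional target most used as a readout of the pathway, had 13 and 10 counts, under the minimum for testing, with a counting interval of −1.20 to 1.45, and GLI2 and the ligand gene SHH had 0 counts in both libraries, below the floor of 3 counts (0.136 CPM on the TMM scale in DMSO and 0.196 in THZ1). The list median was −0.63, at percentile 11.35 among 10000 random lists matched on mean expression, as a description of these libraries.

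Among 14 tested stemness-associated genes, 5 were lower, 1 was higher and 8 were neither, and on the mitochondrial reference 11 were lower and 0 higher. The transcription factor genes SOX9 (−2.35, −2.50 to −2.22; 3506 and 476 counts), KLF4 (−1.84, −2.18 to −1.52) and KLF5 (−1.81, −2.17 to −1.48) were lower, as were ID3 (−1.38) and ID1 (−1.28). ID2 was higher (1.55, 0.99 to 2.16), a ratio below 0 on the mitochondrial reference. MYC (−0.31, −0.43 to −0.20), POU5F1 (−0.05, −0.80 to 0.66), BMI1 (−0.03, −0.13 to 0.07) and the surface marker CD44 (0.17, 0.15 to 0.20) had ratios within 2-fold. NANOG had 0 counts in both libraries and SOX2 had 2 and 0, so a difference was not detectable at this depth. The list median was −0.04, at percentile 33.81 of the matched random lists.

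**Figure D2:**
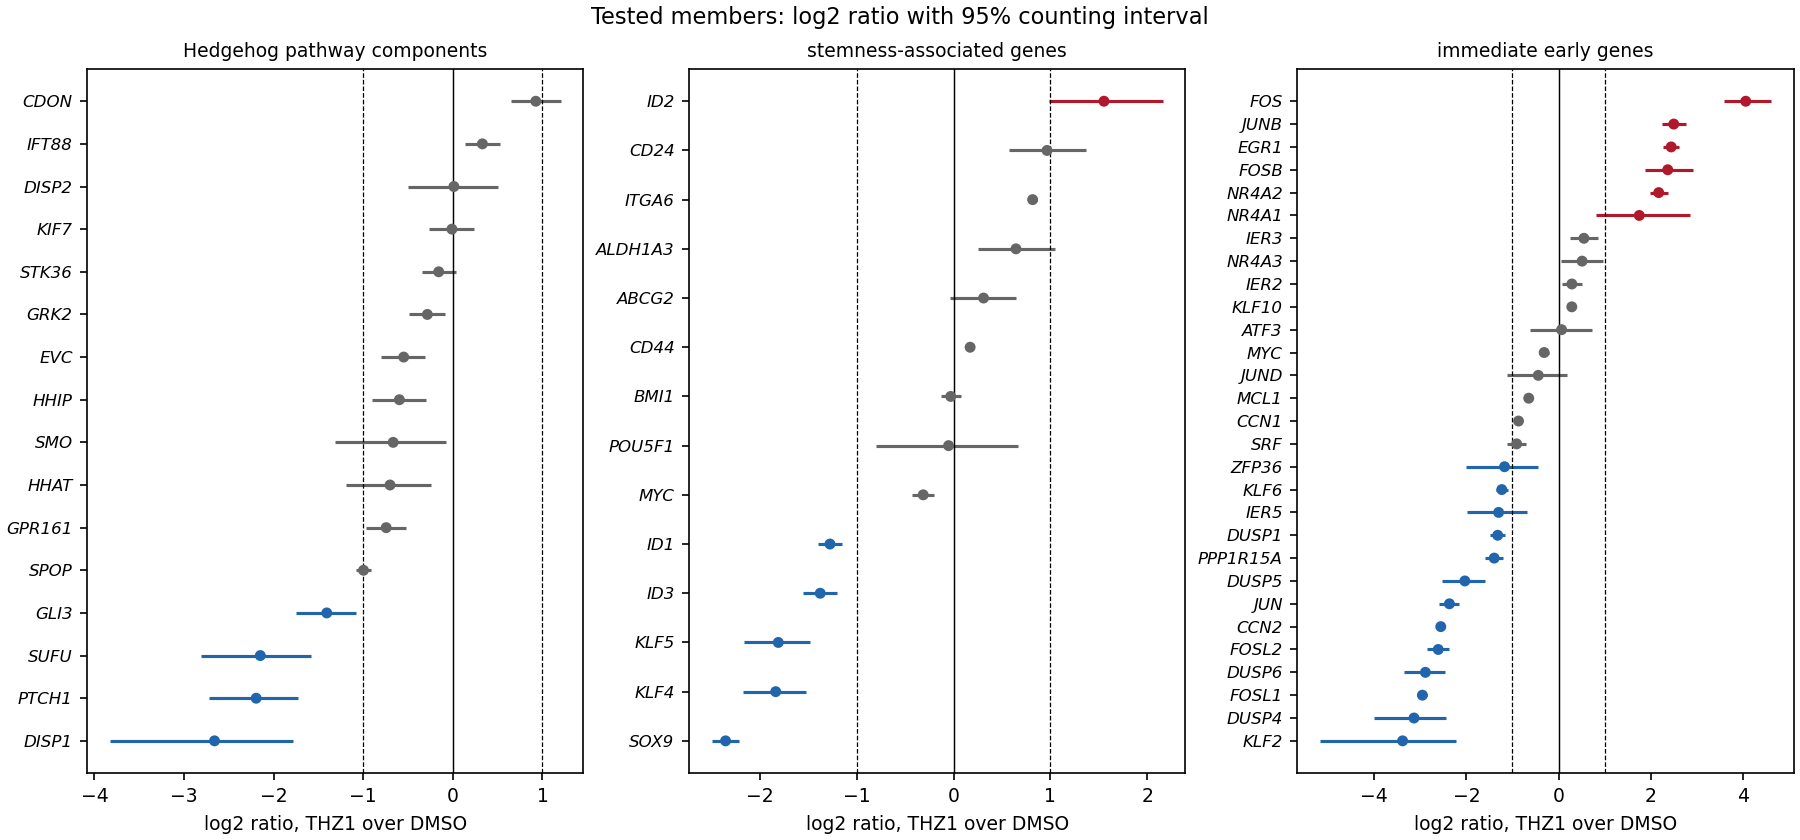
Points are log2 ratios of the THZ1 over the DMSO library (horizontal axis) for the tested members of 3 lists (Hedgehog components, stemness-associated genes and immediate early genes), bars are 95% counting intervals, and dashed lines mark 2-fold. Blue genes were lower, red genes higher and grey genes neither; FOS (4.05) and KLF2 (−3.38) mark the ends of the immediate early panel, and ID2 (1.55) falls below 0 on the mitochondrial reference.

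The transcription machinery that THZ1 targets moved unevenly. CDK7 (ENSG00000134058, chromosome 5 from 69234795 to 69277430) was lower, with a ratio of −1.38 (−1.63 to −1.14; 676 and 180 counts). Its partners in the CDK-activating kinase had ratios of 0.39 (CCNH) and 0.86 (MNAT1), which fall below 0 on the mitochondrial reference and, for CCNH, also with total counts. Of 9 tested TFIIH and CDK-activating kinase genes, 1 (CDK7) was lower, 1 was higher (GTF2H5, 1.28, and −0.41 on the mitochondrial reference) and 7 were neither, with the list median at percentile 74.09. Transcriptional kinases, their cyclins and pause-release factors numbered 26, of which 8 were lower, 1 was higher and 17 were neither. Their median was −0.59, at percentile 0.23, with an interval that reaches above 0 (−1.02 to 0.18). CCNT1, the cyclin of the elongation kinase P-TEFb (−2.48, −2.68 to −2.28), the elongation factor gene ELL (−2.31, −3.10 to −1.66), CDK8 (−1.67), CDK12 (−1.43, −1.56 to −1.31) and CDK13 (−1.02, −1.19 to −0.85) were among the lower genes. With DESeq2 size factors CDK13 had a ratio of −0.99, within 2-fold, and 7 genes of the list were lower. RNA polymerase II subunits showed 1 lower gene (POLR2D, −1.62), 1 higher gene (POLR2I, 1.23, and −0.46 on the mitochondrial reference) and 10 that were neither, at percentile 95.44. The largest subunit POLR2A had a ratio of 0.07 (0.01 to 0.13), which is −0.44 with total counts.

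Immediate early genes, which respond within minutes to growth factors and stress, split in both directions. Of 29 tested, 13 were lower, 6 higher and 10 neither, with a median of −0.87 (−1.40 to 0.29) at percentile 0. FOSL1 (−2.95, −3.06 to −2.85; 8581 and 770 counts) and DUSP4 (−3.13, −4.01 to −2.44) were lower, while FOS, FOSB, JUNB, EGR1, NR4A1 and NR4A2 were higher. On the mitochondrial reference 23 of the list were lower and 1 was higher, and NR4A1 (1.75, 0.80 to 2.84; 13 and 31 counts) was close to 0. NF-kappaB target genes had 9 lower, 0 higher and 9 neither, with a median of −1.16 at percentile 0.05, and included BIRC3 (−2.60, −2.71 to −2.49), the inhibitor gene NFKBIA (−2.08, −2.41 to −1.77) and the cytokine gene LIF (−1.94).

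Among 10 anti-apoptotic genes, BIRC3, BCL2L1 (−1.52, −1.70 to −1.35) and BCL2 (−1.20, −1.43 to −0.98) were lower, 0 were higher and 7 were neither. The list median was −0.52 (−1.52 to 0.32), at percentile 0.64. MCL1, whose mRNA and protein are short-lived, had a ratio of −0.65 (−0.71 to −0.58; 6476 and 2872 counts), within 2-fold on this scaling and lower by the rule with total counts. Among 16 pro-apoptotic genes, 5 were lower, 0 higher and 11 neither, at percentile 6.83, including BAK1 (−3.35) and BOK (−1.70). p53 target genes had 6 lower, 0 higher and 14 neither, at percentile 1.82, among them SESN2 (−4.03, −5.61 to −2.98), AEN (−2.93) and PPM1D (−2.92). CDKN1A, the cyclin-dependent kinase inhibitor gene, had a ratio of −0.74 (−0.96 to −0.53).

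Cell cycle genes contained lower members and none that was higher by the rule. Of 32 G1/S and DNA replication genes, 11 were lower and 21 neither, at percentile 0.47, with CDC25A (−4.60), E2F2 (−3.53, −4.23 to −2.95) and the cyclin gene CCNE2 (−2.67, −3.14 to −2.25) as the members furthest from 0. With DESeq2 size factors 1 member passed the rule as higher. Of 32 G2/M and mitosis genes, 24 were neither and 8 were lower, including the mitotic kinase genes AURKA (2308 and 401 counts) and PLK1 (−1.98) and the cyclin gene CCNA2 (−1.95). The list median of −0.01 was near the −0.03 of all tested genes, with 16 members below the latter and 16 above. Its percentile was 2.61 because the matched random lists had a higher median of 0.29. DNA damage response and homologous recombination genes had 11 lower, 0 higher and 23 neither, with a median of −0.36 (−1.12 to 0.14) at percentile 2.43. PALB2 (−2.53, −2.80 to −2.28), which links BRCA1 to BRCA2, RAD52 (−2.07) and the helicase gene BLM (−1.85) were lower. Among 13 nucleotide excision repair genes, ERCC4 (−2.13) and XPC (−1.39) were lower, CETN2 was higher (1.33, and −0.36 on the mitochondrial reference) and 10 were neither, at percentile 70.03.

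Of 23 Wnt components and targets, 9 were lower, 0 higher and 14 neither, with a median of −0.67 at percentile 2.91. AXIN1 (−3.55, −4.27 to −2.96) and ZNRF3 (−3.10, −3.59 to −2.67), both negative regulators of the pathway, and the receptor gene FZD5 (−3.24, −3.84 to −2.74) were lower. Of 14 Notch components, 5 were lower, 1 higher and 8 neither, at percentile 16.36, with JAG1 (−1.55), MAML2 (−1.43) and NOTCH1 (−1.34) lower. Epithelial-mesenchymal transition genes had 4 lower, 1 higher and 13 neither, and the lower genes included SNAI2 (−2.40) and TGFB2 (−1.56). Their median of −0.19 (−0.48 to 0.45) stood at percentile 2.70, where the matched random lists had a median of 0.26. Among 7 tested urothelial markers, FOXA1 was lower (−2.07, −2.83 to −1.42), 0 were higher and 6 were neither, at percentile 26.73, with EGFR at −0.51 and KRT8 at 0.90.

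Platinum transport and glutathione genes had 7 lower, 0 higher and 16 neither, at percentile 9.68, with HMOX1, the antioxidant regulator gene NFE2L2 (−2.32, −2.47 to −2.18) and its inhibitor KEAP1 (−2.28, −2.70 to −1.91) all lower. Heat shock and chaperone genes had 5 lower, 2 higher and 15 neither, at percentile 37.29: DNAJB1 (−2.86) and BAG3 (−2.40) were lower and HSPE1 (1.76) was higher. In the unfolded protein and integrated stress response list, 7 were lower, 1 was higher and 14 were neither, at percentile 33.48, and SESN2, TRIB3 (−3.34) and XBP1 (−1.88) were lower. Cholesterol synthesis genes had 5 lower, 0 higher and 15 neither, at percentile 55.40, with INSIG1 (−2.74), MVK (−2.45) and SQLE (−2.02) lower. Of 23 hypoxia and glycolysis genes, ADM was lower (−2.31), 4 were higher and 18 were neither, at percentile 91.89. With total counts 2 were lower and 0 higher, and with DESeq2 size factors 6 were higher. The higher genes BNIP3L (1.51) and P4HA1 (1.38) turn to −0.18 and −0.31 on the mitochondrial reference. Interferon-stimulated genes had 2 lower, 2 higher and 11 neither, at percentile 92.08, with DTX3L lower (−1.65), IFI6 higher (1.45, and −0.24 on the mitochondrial reference) and IFITM3 at 0.72. The commonly used reference genes ACTB and GAPDH had ratios of 0.22 and 0.43, which become −0.30 and −0.09 with total counts.

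Splicing factors with poison exons and CLK kinases had 3 lower, 0 higher and 18 neither, beside 21.3% lower among all tested genes. Their median was −0.46 (−0.91 to 0.21) at percentile 0, where the matched random lists had a median of 0.45. The lower genes were CLK4 (−2.96, −3.34 to −2.61), CLK1 (−2.30, −2.45 to −2.16) and SRSF4 (−1.55, −1.67 to −1.44). With the upper quartile 5 of that list were lower. Small nucleolar RNA host genes had 6 lower, 2 higher and 10 neither, at percentile 6.79, with SNHG17 (−2.76), SNHG7 (−2.47) and SNHG12 (−2.37) lower, of which SNHG7 and SNHG12 are annotated as antisense genes and are uncertain because no strand setting is given. C2H2 zinc finger genes, a large family of DNA-binding proteins, were represented by the coding genes whose symbol is ZNF followed by digits. Values for these genes need not hold for the whole family. Of the 395 tested, 239 were lower (60.5%), 3 higher and 153 neither. Their median was −1.28 (−1.41 to −1.16), at percentile 0 with matching on mean expression and also with gene length added. Coding genes without introns had 72 of 161 lower and 36 higher, with a median of −0.80 (−1.22 to −0.33) at percentile 0. Without histone genes that median was −1.16, with 72 of 140 lower and 23 higher.

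The lists with the highest medians were those of mitochondrially encoded mRNAs, replication-dependent histones, ribosomal proteins and the respiratory chain, whose medians lie above 0 on the main scaling and below 0 on the mitochondrial reference. On that reference COX6A1 and the histone gene H4C3 (4.23 on the main scaling; 6 and 84 counts) were still higher by the rule. Of 63 cytosolic ribosomal protein genes, 0 were lower, 36 higher and 27 neither, and the median was 1.06 (0.91 to 1.14), or −0.63 with 13 lower and 0 higher on the mitochondrial reference. RPS29 (2.15), RPS21 (1.94) and RPL26 (1.87) had the highest ratios among them. Nuclear-encoded respiratory chain genes had 0 lower, 16 higher and 20 neither, with a median of 0.90 (−0.79 on the mitochondrial reference) and COX6A1, COX6C (1.85) and COX7C (1.75) at the top. Replication-dependent histone genes, whose mRNAs mostly lack the poly(A) tail, had 0 lower, 15 higher and 3 neither, with a median of 1.26 (−0.43 on the mitochondrial reference), and after H4C3 the named genes H4C5 (2.52), H2AC8 and H2BC8 (1.90) followed. A difference between the libraries in the capture of such mRNAs was not tested and cannot be told apart from the treatment. Against the 5 nearest genes in transcript length, GC content and mean expression, the median difference was 0.31 for ribosomal protein and 0.49 for respiratory chain genes. Ribosomal protein and histone genes have many near-identical copies or pseudogenes, so their single values are uncertain. Each of these lists stood at percentile 100, whereas 10 replication-independent histone genes stood at percentile 46.98 with H2AX lower (−1.13), H2AJ higher (1.29, and −0.40 on the mitochondrial reference), H2AZ1 at 0.84 and 8 neither.

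All 13 mitochondrially encoded mRNAs were higher, with a median of 1.64 at percentile 100, and −0.05 with 0 lower and 0 higher when the list itself is the reference. MT-ND3 (2.25), MT-CO3 (1.90) and MT-ND5 (1.89) had the highest ratios. Mitochondrially encoded genes took 8.75% (8.73% to 8.76%, exact binomial) of the DMSO counts and 19.9% (19.8% to 19.9%) of the THZ1 counts, and the 10 most abundant genes took 9.49% and 19.8%. Mitochondrial rRNA alone took 2.12% and 4.90%. Of 15 tested mitochondrial tRNA genes, 12 were higher and 0 lower, with a median of 1.30 that is below 0 on the mitochondrial reference. Other RNA classes that mostly lack a long poly(A) tail had few tested genes: 4 of 6 genes of the miscellaneous class were higher and 2 lower, 2 of 5 snoRNA genes were higher and 1 lower, and 2 of 4 snRNA genes were higher and 1 lower. Of 4 miRNA genes, 3 were higher and 1 lower. The 5.8S rRNA genes RNA5-8SN1 (0 and 41 counts) and RNA5-8SN3 (0 and 192 counts), which have several copies and are uncertain, were both higher. The kit captures polyadenylated RNA, and how far each library took up RNA without a tail was not measured. With 1 library per group this cannot be told apart from the treatment. Markers of other cell types were scarce: 0 of 12 blood cell markers and 0 of 9 endothelial markers reached the count minimum. Of 12 fibroblast markers 4 did, with 0 lower, LUM higher (1.54, and below 0 on the mitochondrial reference) and 3 neither, at percentile 62.95. With total counts 1 of the 4 was lower, and with the mitochondrial reference 3 were.

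**Figure D3:**
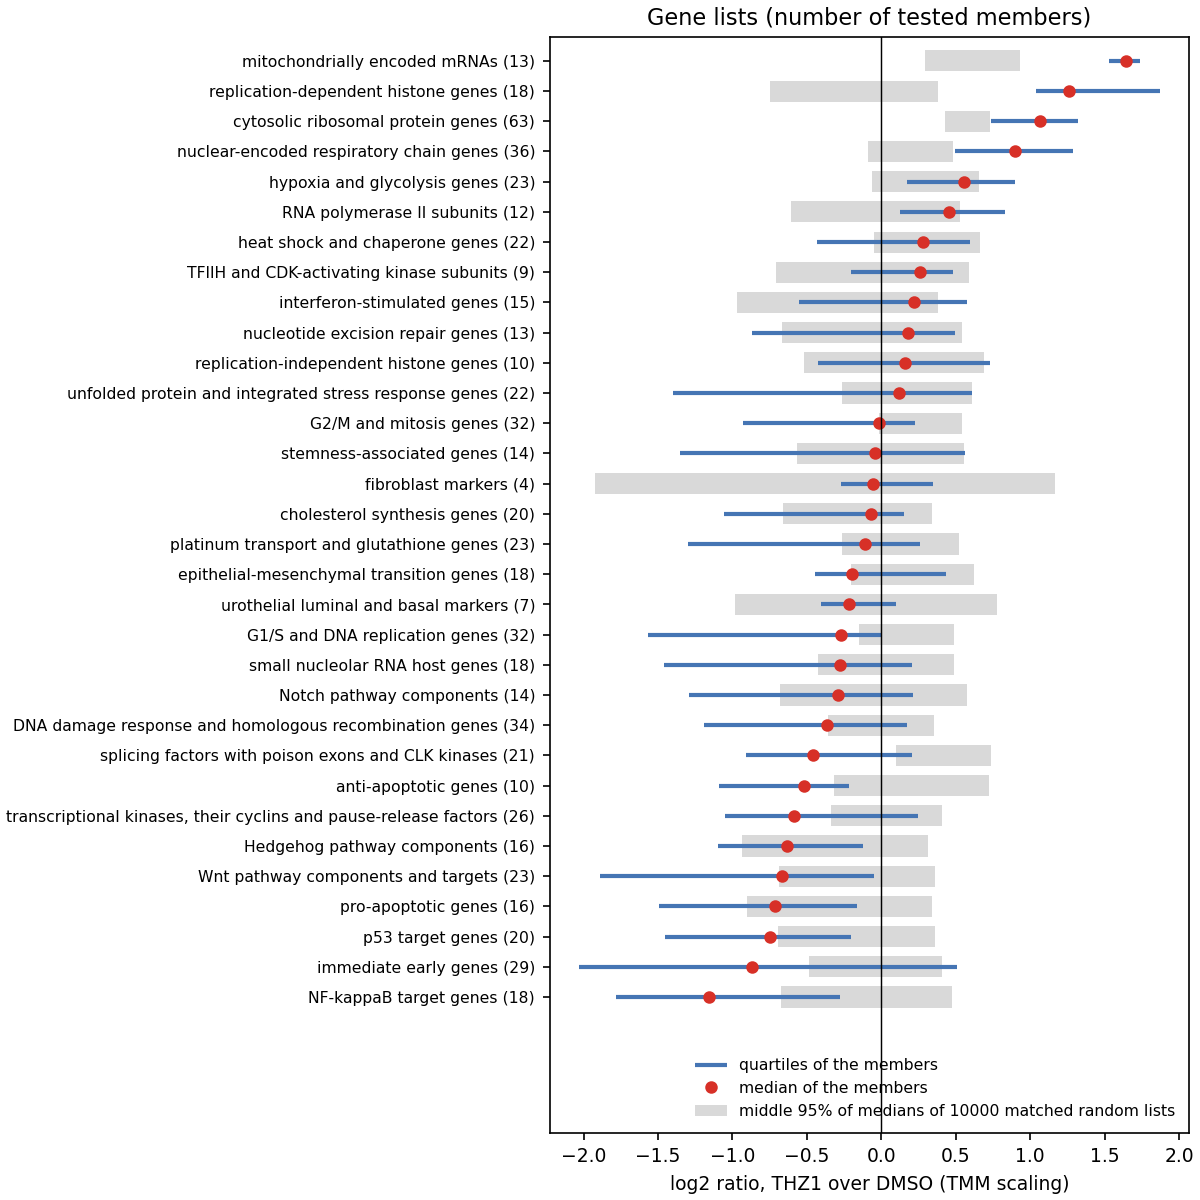
For each list with 3 or more tested members (number in parentheses), the red point is the median log2 ratio of the THZ1 over the DMSO library, the blue line the quartiles of the members and the grey bar the middle 95% of medians of 10000 random lists matched on mean expression. NF-kappaB targets (−1.16) and immediate early genes (−0.87) lie to the left of their bars, while mitochondrially encoded mRNAs (1.64), replication-dependent histones (1.26), ribosomal proteins (1.06) and respiratory chain genes (0.90) lie to the right, at −0.05, −0.43, −0.63 and −0.79 on the mitochondrial reference.

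Gene span went with small differences in the median ratio and with a larger difference in the share of lower genes. Across 10 equal-sized bins of gene span, the median of coding genes was −0.06 in the shortest bin, −0.20 in the third and 0.16 (0.09 to 0.21) in the longest, which starts at 161743 bp. The share of genes called lower was 26.5% in the shortest bin of span, 27.4% in the fourth and 13.6% in the longest. With exonic length in place of span the difference in median between the longest and the shortest bin reversed to −0.45. The share called lower was then 16% in the shortest bin, 27% in the sixth and 17% in the longest. Transcript length and GC content showed wider ranges: the median was 0.51 (0.47 to 0.56) for transcripts of 207 to 1306 bases and −0.15 (−0.20 to −0.08) for those of 7233 bases or more, and it was 0.27 in the bin with the lowest and −0.37 in the bin with the highest GC content.

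**Figure D4:**
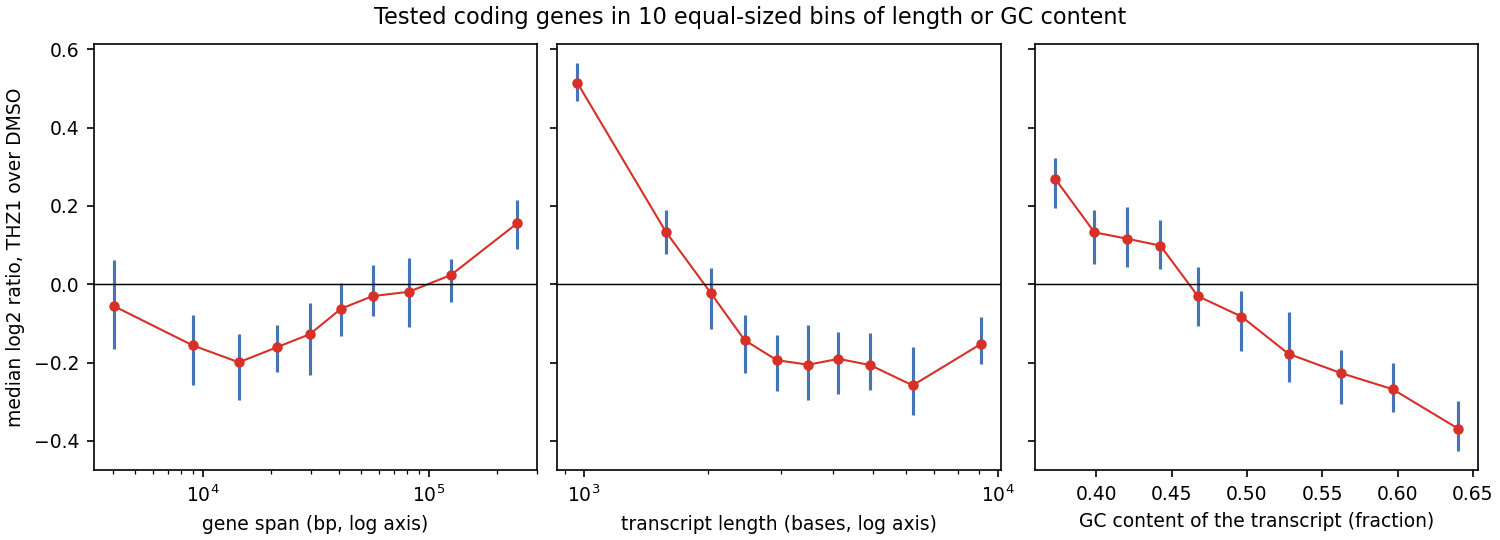
Points are the median log2 ratio of the THZ1 over the DMSO library (vertical axis) in 10 equal-sized bins of tested coding genes by gene span in bp (left, log axis), transcript length in bases (middle, log axis) and GC content as a fraction (right), and bars are 95% order-statistic intervals of the median over genes. Short transcripts lie highest (0.51) and GC-rich transcripts lowest (−0.37), and all of these medians are about 0 or below with total counts and below 0 on the mitochondrial reference.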

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

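The correction for transcript length and GC content was chosen after the trends were seen, and the other alternatives before. The size of the ratios depends on the scaling, as does the direction of those above 0 by less than its shift, since the libraries differ in composition. With total counts, 4260 genes were lower and 368 higher, and the median of all tested genes was −0.54. With mitochondrially encoded mRNAs as the reference, 10000 genes were lower and 88 higher, and the median was −1.72. With this reference 7 of the ratios that the naming rule gives as higher were below 0: GTF2H5 (−0.41), POLR2I (−0.46), CETN2 (−0.36), IFI6 (−0.24), BNIP3L (−0.18), P4HA1 (−0.31) and H2AJ (−0.40). Ratios above 0 by less than 1.69 that were neither, among them CCNH, MNAT1, CD44, ACTB and GAPDH, were below 0 as well. These reversals follow from the reference, which lowers every ratio by the same amount, and the data hold no spike-in that would choose between references. The median of all genes was 0.0015 with DESeq2 size factors, −0.062 with the upper quartile, 0.086 with a minimum of 1 count and −0.064 over protein-coding genes only. A minimum of 1 count gave 2223 higher genes, most of the added ones resting on few counts by construction, and an interval bound of at least 2-fold gave 670. With exonic length in place of gene span, the difference between the longest and the shortest bin was −0.45, and the cause was not tested. Corrected for transcript length and GC content, the median above all genes was 0.59 for ribosomal protein genes, 0.57 for respiratory chain genes and 0.86 for hypoxia and glycolysis genes.

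Relative to the median of all genes, all 32 list medians were within their main interval under each of the other scalings, filters and the larger prior count where they could be computed, since a scaling moves a list and all genes alike. Of 122 named ratios, all moved beyond their counting interval with the mitochondrial reference, 94 with total counts, 5 each with DESeq2 size factors and the upper quartile, and 0 with other filters or the larger prior count. The numbers of lower or higher members changed by over 1.5 times in 29 of 64 cases with total counts and in 50 with the mitochondrial reference. Such changes also came in 4 cases each with count minimums of 1 and 100 and in 2 with protein-coding genes only. DESeq2 size factors and the upper quartile gave 1 each. Matching the random lists on gene length as well moved 4 percentiles across 2.5: Wnt components to 1.04, G2/M genes to 0.87, small nucleolar RNA host genes to 1.86, and DNA damage response genes to 4.33 from 2.43. No paired analysis was possible because each group has 1 library, and leaving out a replicate could not be run for the same reason. Depth limits the low genes: GLI2, SHH, SOX2 and NANOG were under the floor of 3 counts, so their response could not be read, and GLI1 (13 and 10 counts) was under the minimum of 30 with a counting interval of −1.20 to 1.45.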

Other observations

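The grouping of genes by the letters of their symbols, the short gene span test, the neighbour test of the immediate early genes and the genes named here were chosen after the results were seen. Collagen genes stood out on the higher side: of 17 tested, 8 were higher and 0 lower, with a median of 0.87 at percentile 100 of the matched random lists, although every ratio among them lies below 0 on the mitochondrial reference. COL4A5, a basement membrane collagen gene, had a ratio of 1.36 (1.24 to 1.48; 909 and 1621 counts), and COL13A1 one of 1.63 (1.33 to 1.94; 132 and 285 counts). Genes of intraflagellar transport, the traffic along the primary cilium in which Hedgehog signalling takes place, had 3 of 15 higher and 0 lower, with a median of 0.57 at percentile 99.63 that is also negative on the mitochondrial reference. IFT80 (1.38, 1.25 to 1.52), IFT25 (1.24, 1.12 to 1.37) and IFT81 (1.17, 1.04 to 1.30) were the higher members. On the lower side, 9 of 16 DUSP genes, a group that includes phosphatases that act on mitogen-activated protein kinases, were lower and 0 higher, with a median of −1.26 at percentile 0.26. KLHL genes, which include substrate adaptors of cullin ubiquitin ligases, had 13 of 22 lower and 2 higher, with a median of −1.17 at percentile 0.10. These are 4 of 74 symbol families with 15 or more tested members.

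Of 407 antisense genes 22.9% were higher and 18.7% lower, of 359 long intergenic RNA genes 22.8% and 10.6%, and of 10881 coding genes 7.61% and 22.0%. Of 170 transcribed unprocessed pseudogenes 7.06% were higher and 25.3% lower. The nuclear RNA NEAT1, the scaffold of paraspeckles, had a ratio of 2.77 (2.73 to 2.80; 7548 and 35693 counts) and stayed above 0 under each scaling tried. MALAT1, an RNA of nuclear speckles, had 112244 and 221087 counts, a ratio between 1.49 and 1.51 that is below 0 on the mitochondrial reference. Processed pseudogenes were higher in 47.0% of 183 cases, and their reads can come from their parent genes.

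Ribosomal protein and respiratory chain genes stood above other genes, and their transcripts are short, as were the coding transcripts with the highest median. Against the 5 nearest coding genes in transcript length, GC content and mean expression, the median difference of the 99 genes was 0.35 (0.22 to 0.49). It was 0.31 for ribosomal protein genes, whose median is 1.06, and 0.49 for respiratory chain genes, whose median is 0.90. Transcript length and GC content may thus account for part of the pattern, through RNA fragmentation or size selection that differed between the libraries, or because mRNAs of this kind were lost more slowly. With 1 library per group these cannot be told apart.

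FOS, FOSB, JUNB, EGR1, NR4A1 and NR4A2 were higher while 13 other immediate early genes were lower. For a short gene span as the reason, the rule asked that most of the 21 tested immediate early genes with a span under 10 kb be higher. Only 6 genes of the list were higher, so the rule could not be met and no conclusion is drawn from it. A short span alone did not separate the higher from the lower genes: of these 21, 4 were higher and 10 lower. Transcript length and GC content as the reason are argued against by the genes nearest to them in these and in mean expression: the neighbours of the 6 higher genes had a median ratio of −0.41 and those of the 13 lower genes −0.11, a difference of −0.31 where the members themselves differ by 4.77, and the highest of the 6 neighbour medians was −0.21. A response of these cells to the compound stays open as a hypothesis, and a difference in handling of the cultures before lysis may also raise such genes, which 1 library per group cannot separate.

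The higher share of antisense and long intergenic RNA genes (22.8% of 766) was not a matter of few counts, because coding genes matched on mean expression reached 9.27% at the median, and the middle 95% of the matched sets ended at 11.4%. Among the 337 of these genes that overlap no coding gene, 27.6% (22.9% to 32.7%) were higher, above the matched bound of 12.2%, which argues against reads from overlapping coding genes as the source for them. Genes that start within 1 kb of a coding gene start on the opposite strand were higher in 25.7% of 249 cases and the others in 21.5% of 517, a difference of 4.23 percentage points whose intervals overlap. Divergent transcription from coding promoters may therefore contribute and stays open, as do slower loss of nuclear RNA and transcripts that run past gene ends, which were not tested. The coding sets were matched on mean expression and not on transcript length. Of the coding genes in the bin with the shortest transcripts (207 to 1306 bases), 23.99% were higher, close to the share of the noncoding genes. Short transcripts as a reason for that share were not tested and stay open too.

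AU-rich elements, which shorten the life of many mRNAs, were compared in the shorter UTRs only: 2483 coding genes with 3 or more ATTTA motifs in the 3 prime UTR lay 0.13 (0.09 to 0.17) above their nearest genes with none in UTR length, GC content and mean expression. The median UTR was 1636 bases in the former and 1183 in the latter. A further 1849 genes with 3 or more motifs had UTRs longer than 99% of those of genes with none and were left out, so 57.3% were compared and a part of these elements in the lower genes stays open.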
